A study of Homo sapiens with 4 samples.

How the data were processed

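Total RNA of human H9-derived neural stem cells treated with PIP-RBPJ-1 at 2 µM or with DMSO for 24 h was extracted with a Qiagen RNeasy Mini kit, and biotin-labelled single-stranded cDNA was hybridised to Affymetrix gene arrays, per the labels' protocols. There were 4 arrays, 2 per group, and the sample titles gave the group and the replicate number. The authors deposited 1 normalized value per probe set and array, here read as log2 values: the labels do not state the base, which was taken from the range of the values and the usual output of the software. The authors used Affymetrix Expression Console, per the submitters' processing notes. Its version, the summarization and background method, the genome build and any filter are not given in the sources used here. An error in the assumed base would rescale each fold change and leave p-values unaltered. Arrays have no read depth, so the number of arrays and the dim signal of many probe sets limit the precision. The deposited values were used as they were, and all 4 value columns were used.

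Of 53617 probe sets, 23862 carried 1 gene symbol in the platform annotation, 1851 carried several and 27904 had no listed gene. Symbols were updated through a RefSeq gene table of assembly GRCh38.p14: 22569 probe sets were matched by Entrez identifier, 724 by current symbol and 565 by synonym, and 4 kept an unmatched symbol. This changed 655 symbols and gave 22351 distinct ones, 661 of them with several probe sets. Probe sets with several symbols or none were left out, and for a gene with several the probe set with the highest mean over the 4 arrays was taken. Genes with a mean at or above the 40th percentile, a value of 2.44, were kept, which left 13411 genes. No coordinates are given, since the build behind the probe sets is not given in the sources used here. Gene span, the length of the locus in the RefSeq table, was used for 13411 genes.

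The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided) on the log2 values with the treatment as the single term, and Benjamini-Hochberg adjusted p below 0.05 was the threshold. Errors of single values are SDs of 2 arrays, and errors of fold changes are limma's standard errors or 95% intervals. The moderated variances had 2 residual and 3.24 prior degrees of freedom. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 over 42 lists with at least 5 measured genes, adjusted over the lists. The lists were written from textbook knowledge before the data were examined, as were the main test, the filter and most of the other settings tried. Python 3.11.15 with pandas 2.3.3 joined the tables and matplotlib 3.10.9 drew the plots.

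The named genes followed a rule fixed in advance. It takes the 10 higher and 10 lower genes with the largest fold change among those passing without overlap, filled up by unadjusted p with genes that do not overlap, a set of Notch, neural and cell cycle genes in any case, and the 3 members of each list with the smallest adjusted p. Genes without an official symbol, small RNAs and sex-linked marker genes were not named, apart from the genes behind counts of 5 or fewer, which were named after their values were seen. The lists whose members are named were chosen after the list results were seen. NEUROD1, which the rule names, was not analysed here, and a further gene of the rule is not reported here.

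The procedure was tested on simulated data with 13411 genes, the real gene means, 2 arrays per group and 200 changed genes. Each gene's variance was drawn at random from limma's fitted prior, and the noise was independent between genes. The procedure recovered 67% of genes changed by 1 on the log2 scale and 91% of those changed by 2. It gave 0 wrong signs and called 10 unchanged genes. An unadjusted p below 0.05 was given to 5.02% of unchanged genes. A list shifted by 0.3 was called with an adjusted p of 3.37e-15 in camera, and 0 unshifted lists were called. Since the noise followed limma's model and was independent between genes, these rates do not cover inter-gene correlation. Recovery at an adjusted threshold also depends on how many genes change and how far, so it does not carry over to the real data. There FAM27E5 had a log2 fold change of 1.01 with an adjusted p of 0.233 in limma. A count of 0 genes passing would thus not show that changes of this size are absent.

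Settings chosen in advance were the replicate number as a block, leaving out each array in turn with the lone array assumed to vary like the other group, no filter or a filter at the 60th percentile, quantile normalization, centring on the array median, eBayes with an intensity trend with and without its robust form, the mean of a gene's probe sets, other thresholds, an estimated inter-gene correlation, and the rotation test fry. Chosen after seeing the data were the removal of a smooth trend with gene span from each array, array weights, leaving out small RNA genes, and a test over all probe sets. A change of sign by less than the standard error, in a gene that no test called, was not counted as a reversal.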

Results

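Gene expression was measured on arrays in human neural stem cells derived from H9, an established embryonic stem cell line. The cells received 2 µM of the compound PIP-RBPJ-1 or the solvent DMSO for 24 h, with 2 arrays per group. RBPJ, from which the compound takes its name, is the DNA-binding factor through which the Notch pathway controls its target genes. Notch activity holds neural stem cells back from becoming neurons, and the comparison asks which genes differ from the DMSO control after 1 day of the compound. Each array gave values for 53617 probe sets on a log scale taken as base 2, with array medians of 2.22 to 2.23, and 13411 genes were tested. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.12. Nothing says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

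After 24 h of PIP-RBPJ-1, genes of the G2 and M phases of the cell cycle and chromatin regulators lay lower as groups, while immediate early genes, glycolytic enzymes and replication-dependent histone genes lay higher as groups. These 5 calls came from camera with a preset inter-gene correlation, and 0 of them held with an estimated correlation (adjusted p = 0.861 for each). With an estimated correlation camera has only the 2 residual degrees of freedom here, so hardly any list could pass. Its unadjusted p for these lists was 0.0553 to 0.2, and it cannot tell whether correlation between genes accounts for the calls. Among single genes, the thyroid hormone-inactivating enzyme DIO3 stood 1.93-fold above DMSO and the small GTPase RND1 1.97-fold above it. RND1 had a low signal of 2.82 in DMSO. The mitotic kinesin KIF14 lay lower by 0.61 on the log2 scale, with a 95% interval of the fold change from -0.85 to -0.36. No gene passed limma's moderated test over all genes. The Notch targets HES5, HES4 and LFNG had higher means after the compound than in DMSO, while HES1, a further Notch target, had a log2 fold change of 0.03.

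Of the 13411 genes tested, 0 were higher and 0 lower at an adjusted p below 0.05 in limma, and the smallest adjusted p was 0.233. The median log2 fold change over all tested genes was 0.05, and 0.006 with quantile normalization. List medians near 0.05 thus mark no shift against the other genes. At an unadjusted p below 0.05 in limma there were 2168 genes, 1605 higher and 563 lower. If genes were independent, 670.6 would be expected by chance. Groups that each mixed DMSO and PIP-RBPJ-1 arrays gave 325 and 297 such genes instead. In mixed groups any difference between DMSO and PIP-RBPJ-1 widens the spread within groups and lowers the count. Those 2 counts are thus no measure of what chance alone would give. With limma's variance trend on intensity, 47 genes were higher and 3 lower, and 21 of these 50 were small RNA genes, all higher. The 3 lower ones were KIF14, the DNA helicase gene BRIP1 and the pseudogene REXO1L1P. With the robust form of that trend, 15 genes were higher and 0 lower. An exact permutation test of 2 arrays against 2 cannot give a p below 0.333. Both PIP-RBPJ-1 arrays lay on one side of both DMSO arrays for 49.5% of genes, against 33.3% by chance.

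There were 387 genes at least 1.5-fold different without overlap between the groups, with 329 higher and 58 lower after PIP-RBPJ-1. Small RNA genes made up 82 of the higher and 14 of the lower ones. At least 2-fold, 23 genes were higher and 3 lower, the latter being REXO1L1P, the pseudogene ROCK1P1 and MIR3671, which were named after their values were seen. The 1.5-fold count was 1038 without DMSO replicate 1 and 396 without DMSO replicate 2, and it was 489 without PIP-RBPJ-1 replicate 1 and 644 without PIP-RBPJ-1 replicate 2. With only genes at or above the 60th percentile of mean signal it was 198.

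The genes with the smallest p in the higher direction were FAM27E5, DIO3, RND1, ETFB, LZTS3, RASA4B, ZNF787, MPP2, MDFI and ZNF696, none of which passed the test (adjusted p = 0.233 for each). DIO3 was at 3.29 ± 0.06 in DMSO and 4.24 ± 0.11 after the compound (mean ± SD of log2 values, n = 2), a log2 fold change of 0.95 ± 0.11 (SE). RND1 stood at 2.82 ± 0.07 and 3.80 ± 0.19, a difference of 0.98 ± 0.13. ETFB, a subunit of the mitochondrial electron transfer flavoprotein, differed by 0.71 ± 0.10. MDFI, an inhibitor of myogenic transcription factors, differed by 0.75 ± 0.11. The log2 fold changes of LZTS3, ZNF787, MPP2 and ZNF696 lay between 0.71 and 0.79. LZTS3, MPP2 and ZNF696, like RND1, had low signals in DMSO, at 2.62, 2.70 and 2.66. FAM27E5 (1.01 ± 0.10) and RASA4B (0.73 ± 0.10) belong to families with near-identical copies, so their probe sets may read more than 1 gene and their values are uncertain. Their DMSO means of 2.37 and 2.205 also lay below the filter value of 2.44.

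In the lower direction the genes were N4BP2L2-IT2, REXO1L1P, KLHL14, FAM72D, KIF14, GOLGA8H, MAG, ZNF654, ZNF449 and PARP14, again with an adjusted p of 0.233 for each. KLHL14 was at 5.23 ± 0.04 in DMSO and 4.51 ± 0.02 after the compound, a log2 fold change of -0.73 ± 0.10. KIF14 was at 7.30 on both DMSO arrays and at 6.70 and 6.69 on the PIP-RBPJ-1 arrays. MAG, which encodes a myelin glycoprotein, had a log2 fold change of -0.64 ± 0.11 at a low signal of 2.87 in DMSO. The log2 fold change was -0.60 ± 0.11 for PARP14, an ADP-ribosyltransferase gene, -0.68 ± 0.12 for ZNF654 and -0.62 ± 0.11 for ZNF449. The intronic transcript N4BP2L2-IT2 was at -0.98 ± 0.11, with a mean of 2.245 after the compound, below the filter value of 2.44. REXO1L1P (-1.31 ± 0.17), FAM72D (-0.63 ± 0.10) and GOLGA8H (-0.65 ± 0.11) have near-identical copies and are uncertain for the same reason.

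The canonical Notch targets had a median log2 fold change of 0.26 over 15 measured genes, 12 of them positive, but as a group they did not pass camera, limma's test of a gene list against all other genes (adjusted p = 0.0643, and adjusted p = 0.861 with an estimated correlation). The 4 targets LFNG, HES4, HES5 and MYC were higher when adjusted over the list alone, against 0 over all genes tested. MYC had a DMSO mean of 2.365, below the filter value of 2.44. HES5, a transcriptional repressor that maintains neural progenitors, was at 5.38 ± 0.37 in DMSO and 6.23 ± 0.09 after PIP-RBPJ-1, a log2 fold change of 0.85 with a 95% interval of 0.36 to 1.34. LFNG, a glycosyltransferase that modifies Notch receptors, differed by 0.69 ± 0.13, and HES4 by 0.68 ± 0.14. HES1 was at 7.02 ± 0.01 and 7.05 ± 0.06, and the 95% interval of its log2 fold change was -0.23 to 0.29. HEY1 and HEY2 lay below the signal filter, with means of 1.72 and 2.11 in DMSO and 1.65 and 2.48 after the compound. Without PIP-RBPJ-1 replicate 2 the list passed, with a median of 0.29 (adjusted p = 0.0484), and with no filter on low values it passed with a median of 0.18 (adjusted p = 0.0265). With the stricter filter its median was 0.06 (adjusted p = 0.251), and with the trend on gene span removed, which is described with the small RNAs, it was 0.16 (adjusted p = 0.406).

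Ligands, receptors, processing enzymes and cofactors of the Notch pathway had a median log2 fold change of 0.08 over 41 genes (adjusted p = 0.864), which was 0.15 without DMSO replicate 1, 0.02 without DMSO replicate 2 and 0.05 without PIP-RBPJ-1 replicate 2. With quantile normalization it was 0.02. The leading members were LFNG, the ubiquitin ligase gene DTX3 at 0.55 ± 0.12 and the gamma-secretase subunit gene PSENEN at 0.44 ± 0.10, none of which passed over all genes. NOTCH1 had a log2 fold change of 0.03 ± 0.11 and its ligand gene DLL1 one of 0.03 ± 0.13. RBPJ itself was at 4.72 on both DMSO arrays and 4.61 ± 0.03 after the compound, and the 95% interval of its log2 fold change was -0.36 to 0.14.

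**Figure D1:**
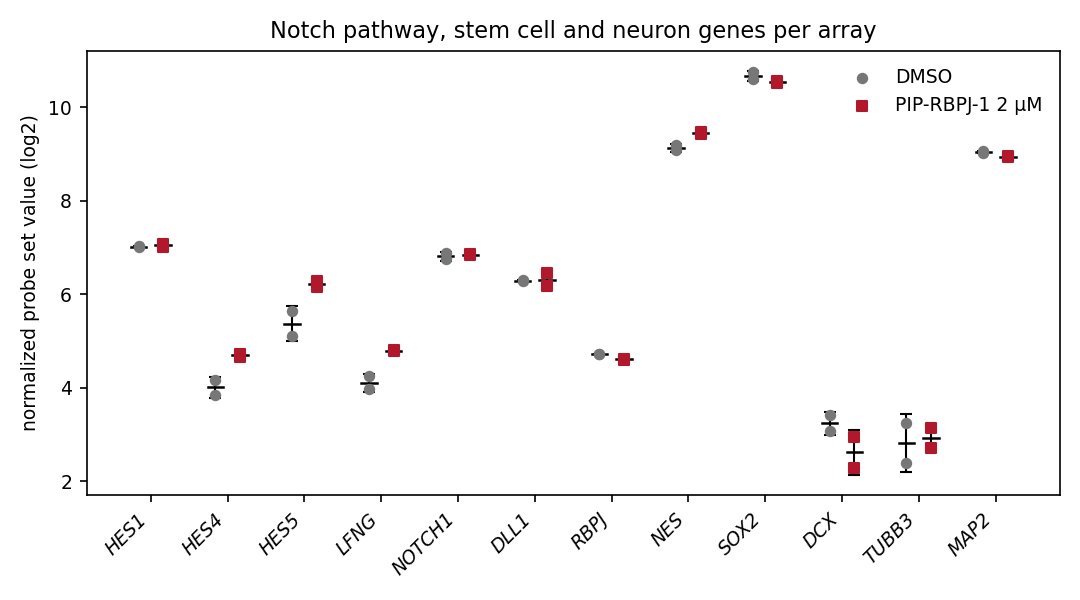
Log2 probe set values (vertical axis) of 12 Notch pathway, stem cell and neuron genes (horizontal axis) on the 2 DMSO arrays (grey circles) and the 2 PIP-RBPJ-1 arrays (red squares), with the mean and SD of each group as black bars. Both PIP-RBPJ-1 arrays lie above both DMSO arrays for HES4, HES5, LFNG and NES, and below both for RBPJ, DCX, MAP2 and SOX2. HES1 lies near 7.02 and 7.05 in the groups.

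Neuronal and neural stem cell markers did not pass camera as groups. Proneural and early neuronal factors had a median log2 fold change of 0.09 over 21 genes (adjusted p = 0.864), led by EBF3 at 0.31 ± 0.10, HES6 at 0.30 ± 0.11 and GADD45G at 0.37 ± 0.14. General neuron markers had a median of 0.11 over 31 genes (adjusted p = 0.384). Among them the neurofilament gene NEFL differed by 0.41 ± 0.11, and the cytoskeletal regulators STMN3 and CRMP1 by 0.50 ± 0.11 and 0.37 ± 0.10. DCX, a microtubule protein of young neurons, was at 3.25 ± 0.25 in DMSO and 2.62 ± 0.48 after the compound, with a 95% interval of the log2 fold change from -1.27 to 0.02. The neuronal tubulin gene TUBB3 varied between the DMSO arrays, at 2.83 ± 0.62, and its log2 fold change was 0.11 ± 0.31. Those of NEUROG2 and MAP2 were -0.09 ± 0.18 and -0.10 ± 0.10. NEUROD1 was not analysed here. The proneural median was -0.01 without PIP-RBPJ-1 replicate 1, 0.17 without PIP-RBPJ-1 replicate 2 and 0.05 without DMSO replicate 2, and the neuron median was 0.17 without DMSO replicate 1 and 0.04 without DMSO replicate 2. The neuron median was 0.02 over 39 genes with no filter and 0.0175 over 16 genes with the stricter one, and the proneural median was 0.01 with the span trend removed.

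Neural stem cell and radial glia markers had a median log2 fold change of -0.07 over 27 genes (adjusted p = 0.193), which was -0.04 without PIP-RBPJ-1 replicate 2 and 0.0049 with the span trend removed. NES, the intermediate filament gene of neural progenitors, was at 9.14 ± 0.08 in DMSO and 9.46 ± 0.02 after PIP-RBPJ-1, a log2 fold change of 0.32 ± 0.10 (adjusted p = 0.262). SOX2 and PAX6, transcription factors of neural stem cells, had log2 fold changes of -0.13 ± 0.11 and -0.01 ± 0.12. The membrane protein gene TTYH1 differed by 0.50 ± 0.11, and LIN28B and PLAGL1 both had a log2 fold change of -0.33 ± 0.10. The signal of the astrocyte gene GFAP lay below the filter in both groups, at 2.32 and 2.12.

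Markers of other cell types did not pass either. The medians were 0.11 for 15 astrocyte markers (adjusted p = 0.864), 0.12 for 10 oligodendrocyte lineage markers (0.877) and -0.07 for 7 markers of pluripotent cells (0.474). They were 0.13 for 9 neural crest markers (0.864), 0.07 for 17 mesenchymal markers (0.812), 0.13 for 8 endothelial markers (0.564) and 0.09 for 11 markers of non-neural germ layers (0.864). Single arrays moved several of these medians: without DMSO replicate 2 the astrocyte median was -0.04, the endothelial one -0.02 and the neural crest one 0.04, and without DMSO replicate 1 they were 0.18, 0.29 and 0.17. Without PIP-RBPJ-1 replicate 1 the astrocyte median was 0.01 and the endothelial one 0.19, and without PIP-RBPJ-1 replicate 2 they were 0.21 and 0.08, with 0.13 for mesenchymal and 0.01 for pluripotency markers. The oligodendrocyte median was 0.20 without DMSO replicate 1. With no filter on low values the neural crest median turned to -0.11 over 18 genes and with the stricter filter to -0.12, and the pluripotency median was -0.005 in both. With the span trend removed the medians were 0.03 for neural crest, 0.04 for astrocyte, 0.01 for non-neural germ layer and 0.15 for mesenchymal markers.

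G2 and M phase genes fell as a group after PIP-RBPJ-1, with a median log2 fold change of -0.13 over 55 genes (camera adjusted p = 4.61e-05, and adjusted p = 0.861 with an estimated correlation). Of these, 38 had a negative fold change, 31 lay lower on both PIP-RBPJ-1 arrays than on both DMSO arrays, and 0 passed alone, whether adjusted over all genes or adjusted over the list alone. Those with the smallest p were CKAP2L at -0.46 ± 0.11, which encodes a spindle protein, the condensin gene SMC4 at -0.40 ± 0.10 and the kinesin gene KIF20B at -0.41 ± 0.11. The list also passed in the lower direction without each array in turn. The rotation test fry, which asks whether a list's genes move one way on balance and compares them with no other genes, did not call it (adjusted p = 0.169).

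Genes of the G1/S transition had a median of -0.04 over 46 genes and did not pass (adjusted p = 0.0583). Their median was -0.02 without DMSO replicate 1, -0.08 without DMSO replicate 2 and -0.02 with the span trend removed. With limma's intensity trend they passed in the lower direction (adjusted p = 0.0453, and adjusted p = 0.861 with an estimated correlation). BRIP1 was at 8.18 ± 0.08 in DMSO and 7.66 ± 0.06 after the compound. The chromatin remodeller HELLS and the replication factor DSCC1 had log2 fold changes of -0.40 ± 0.12 and -0.42 ± 0.13. DNA damage and repair genes had a median of -0.06 over 41 genes (adjusted p = 0.0643), which was -0.005 without DMSO replicate 1, -0.035 without DMSO replicate 2 or PIP-RBPJ-1 replicate 1, and -0.013 with the span trend removed.

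Chromatin regulators fell as a group, with a median log2 fold change of -0.09 over 41 genes, 28 of them negative (camera adjusted p = 0.006, adjusted p = 0.861 with an estimated correlation, and adjusted p = 0.0228 in fry). The demethylation enzyme gene TET1 had a log2 fold change of -0.31 ± 0.10, the histone methyltransferase gene KMT2C one of -0.29 ± 0.10 and the remodeller CHD7 one of -0.28 ± 0.10. The call was lost without DMSO replicate 2 (median -0.08, adjusted p = 0.0869) and with no filter on low values (median -0.08, adjusted p = 0.0566), both at a similar median. It was also lost with the trend on gene span removed, which left a median of -0.01 (adjusted p = 0.433).

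Immediate early genes, which cells switch on within minutes of a stimulus, rose as a group with a median log2 fold change of 0.27 over 28 genes (camera adjusted p = 0.00221, and adjusted p = 0.861 with an estimated correlation). Of these, 26 were positive, and 2, JUN and EGR3, were higher when adjusted over the list alone, against 0 over all genes. JUN, a subunit of the AP-1 transcription factor, was at 6.01 ± 0.08 in DMSO and 6.70 ± 0.09 after the compound, a log2 fold change of 0.69 ± 0.11. EGR3 differed by 0.64 ± 0.11 and MYC by 0.57 ± 0.15, the latter with a DMSO mean of 2.365, below the filter value of 2.44. The list did not pass without DMSO replicate 1, where its median was 0.30 (adjusted p = 0.0596), or with the span trend removed (median 0.26, adjusted p = 0.0774), nor in fry (adjusted p = 0.176).

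Glycolytic enzymes rose as a group, with a median of 0.26 over 17 genes, 15 of them positive (camera adjusted p = 0.006, and adjusted p = 0.861 with an estimated correlation). TPI1 differed by 0.91 ± 0.28, PFKP by 0.35 ± 0.12 and GAPDH by 0.33 ± 0.11, and 0 members passed when adjusted over the list alone. Without DMSO replicate 1 the list did not pass at the same median of 0.26 (adjusted p = 0.0748), and fry did not call it (adjusted p = 0.143). Subunits of oxidative phosphorylation had a median of 0.13 over 33 genes (adjusted p = 0.0958, and adjusted p = 0.861 with an estimated correlation). The median was 0.115 without DMSO replicate 1. They did not pass camera with quantile normalization (median 0.09, adjusted p = 0.173) or with the span trend removed (median 0.11, adjusted p = 0.503). They passed without DMSO replicate 2 (adjusted p = 0.0313), with no filter (0.0353) and with the intensity trend (0.0453), and fry, which compares them with no other genes, called them too (0.0228). Cytosolic ribosomal proteins had a median of 0.14 over 30 genes (adjusted p = 0.193), which was 0.07 without PIP-RBPJ-1 replicate 2 and 0.04 with the span trend removed, where camera's direction was lower.

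Replication-dependent histone genes rose as a group, with a median of 0.31 over the 12 genes measured, all positive (camera adjusted p = 0.006, and adjusted p = 0.861 with an estimated correlation). H2BC17, H2BC13, H2BC9 and H2BC3 were higher when adjusted over the list alone, against 0 over all genes. H2BC17 differed by 0.84 ± 0.12, H2BC13 by 0.68 ± 0.15 and H2BC9 by 0.75 ± 0.19. These genes are near-identical copies, so probe sets may read several of them. With the span trend removed the median was 0.21 and the list did not pass (adjusted p = 0.0999), and fry did not call it (adjusted p = 0.176).

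**Figure D2:**
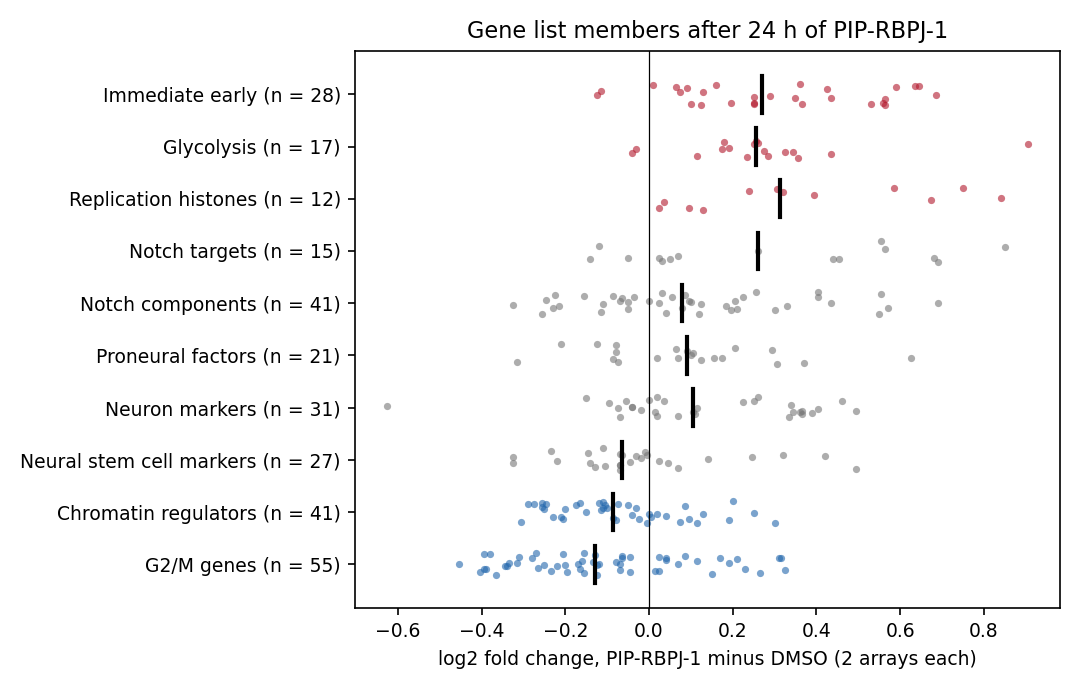
Log2 fold changes after PIP-RBPJ-1 against DMSO (horizontal axis) of the members of 10 gene lists (vertical axis), 1 point per gene, with the list median as a black bar. Lists that passed camera are red when higher and blue when lower, and the medians run from -0.13 for G2/M genes to 0.31 for replication histones.

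Stress and signalling genes gave single members with high fold changes and no list that passed. Targets of p53 had a median of 0.07 over 35 genes (adjusted p = 0.462), and of 0.14 without PIP-RBPJ-1 replicate 2. The cell cycle inhibitor CDKN1A differed by 0.46 ± 0.13 (adjusted p = 0.248), the apoptosis genes BAX and BBC3 by 0.48 ± 0.11 each. Genes of endoplasmic reticulum stress had a median of 0.08 over 31 genes (adjusted p = 0.474), which was 0.02 without DMSO replicate 2 and 0.14 without PIP-RBPJ-1 replicate 2, and 3 of them were higher when adjusted over the list alone, namely DDIT3 at 0.85 ± 0.14, DDIT4 at 0.74 ± 0.13 and SDF2L1 at 0.55 ± 0.11. Interferon-stimulated genes had a median of 0.24 over 13 genes (adjusted p = 0.179, and adjusted p = 0.861 with an estimated correlation). The median was 0.33 over 8 genes with the stricter filter, where the list passed (adjusted p = 0.0289), 0.0075 over 32 genes with no filter (adjusted p = 0.563) and 0.14 with the span trend removed (adjusted p = 0.517). Of the interferon-stimulated genes, 3 were higher when adjusted over the list alone, namely IFITM1 at 0.80 ± 0.12, IFI6 at 0.69 ± 0.12 and IFITM3 at 0.62 ± 0.12. Cholesterol synthesis genes had a median of 0.10 over 22 genes (adjusted p = 0.297), and the kinases MVK and PMVK differed by 0.63 ± 0.11 and 0.73 ± 0.13, the sterol reductase TM7SF2 by 0.61 ± 0.12. In that list 3 genes were higher and 1 lower when adjusted over the list alone.

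Host genes of small nucleolar RNAs had a median of 0.22 over 11 genes (adjusted p = 0.414), which was 0.11 without DMSO replicate 1 and 0.12 with the span trend removed. The other 16 lists had medians between -0.04 and 0.12 and adjusted p between 0.435 and 0.998, with medians between -0.05 and 0.23 when an array was left out. They covered synapse, apoptosis, heat shock, NRF2, xenobiotic, hypoxia, NF-kB, ERK feedback, Wnt, BMP and TGF-beta, Sonic hedgehog, YAP, extracellular matrix, axon guidance, ribosome biogenesis and short-lived mRNA genes. With the span trend removed the medians ran from -0.012 to 0.176. The axon guidance median then moved from 0.065 to 0.176, and the extracellular matrix one turned from -0.0125 to 0.083. For the synapse, heat shock, xenobiotic, ERK feedback, BMP and TGF-beta and Sonic hedgehog lists the median was positive while camera's direction was lower, and ribosome biogenesis genes had a median of -0.04 and a mean of 0.02.

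Small nucleolar RNAs, which guide chemical modification of other RNAs, had a median log2 fold change of 0.34 over 112 genes. Of these, 97 were positive and 65 lay higher on both PIP-RBPJ-1 arrays, against 4 lower on both. Spliceosomal and other small nuclear RNAs had a median of 0.55 over 15 genes, and microRNA genes one of 0.07 over 263. With the span trend removed the medians were 0.23 for small nucleolar RNAs, 0.44 for small nuclear RNAs and -0.04 for microRNA genes, the last with its sign turned.

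The fold change also followed the length of the gene in the genome. Across genes, which are not independent replicates, Spearman's rho of log2 fold change with gene span was -0.336 over the tested genes and -0.379 over 11738 protein-coding genes. In 5 equal bins of protein-coding genes by span, the median log2 fold change was 0.19 at a median span of 4.73 kb, 0.12 at 14.1 kb, 0.04 at 29.4 kb, -0.02 at 59.2 kb and -0.06 at 160.2 kb. The 4 pairs of a PIP-RBPJ-1 array with a DMSO array gave rho between -0.309 and -0.248, while the replicate pairs gave 0.0496 in DMSO and 0.085 in PIP-RBPJ-1.

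**Figure D3:**
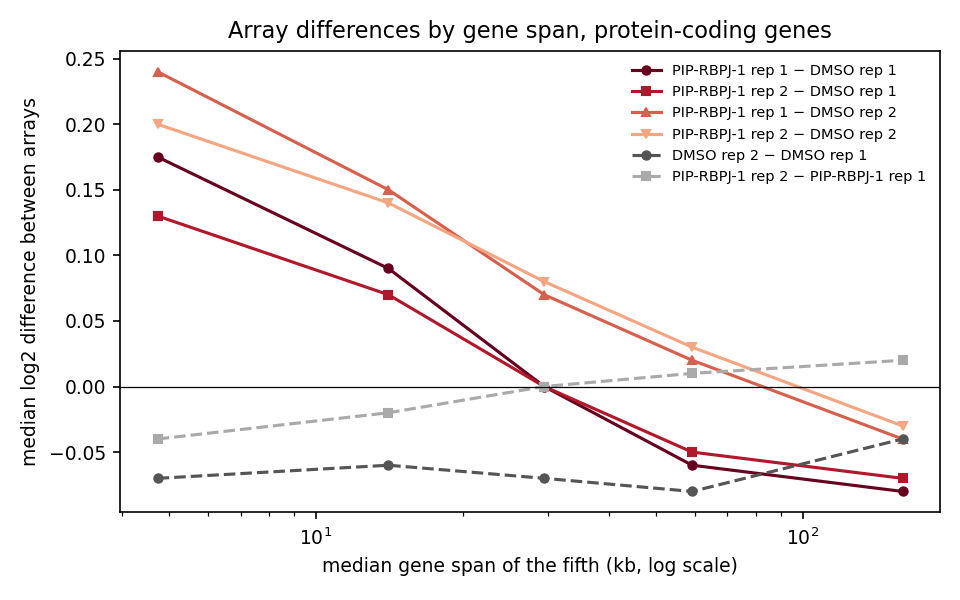
Median log2 difference between 2 arrays (vertical axis) in 5 equal bins of protein-coding genes by gene span (horizontal axis, kb, log scale). Solid lines are PIP-RBPJ-1 minus DMSO arrays and dashed lines replicate pairs, and from the shortest to the longest genes the solid lines run from between 0.13 and 0.24 down to between -0.08 and -0.03.

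The arrays of a group resembled each other more than those of different groups, with an exception for DMSO. Pearson's r over the 13411 tested genes was 0.993 between the PIP-RBPJ-1 arrays and 0.988 between the DMSO arrays. DMSO replicate 1 correlated at 0.987 and 0.989 with the PIP-RBPJ-1 arrays, and DMSO replicate 2 at 0.983 and 0.985. The SD across genes of the replicate difference was 0.28 in DMSO and 0.22 in PIP-RBPJ-1, and that of the difference of group means was 0.25. The last compares means of 2 arrays, not single arrays, so independent noise alone would give it a lower SD than the replicate differences. The first principal component held 54.7% of the variance, with scores of -4.84 and -23.4 for the DMSO arrays and positive scores for both PIP-RBPJ-1 arrays.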

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

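The alternatives on gene span, array weights, small RNA genes and all probe sets were chosen after seeing the data. Of 1313 recomputed fold changes of 89 named genes, 1301 kept their side of the threshold with no counted reversal. These include changes of sign by less than the standard error. Another 7 newly passed, all with an intensity trend (BRIP1, KIF14, REXO1L1P, JUN, H2BC17, and IFITM1 in both forms), and 5 turned over by more than the standard error. The last were DLL1, at -0.105 to 0.155 when arrays were left out, NEUROG2 at -0.325 to 0.155 and TUBB3 at -0.33 to 0.54, and RBPJ at 0.0035 and MAP2 at 0.018 with the span trend removed. The intensity trend gave 47 genes higher after PIP-RBPJ-1 and 3 genes lower after PIP-RBPJ-1, and its robust form 15 higher, where the main setting gave 0. Other settings gave 0 genes, among them all 53617 probe sets (smallest adjusted p 0.364, with 3912 at an unadjusted p below 0.05). There were 387 genes at least 1.5-fold different without overlap, 198 with the stricter filter, which tests fewer genes, and 396 to 1038 with an array left out (396 without DMSO replicate 2 and 1038 without DMSO replicate 1). Gene lists higher after PIP-RBPJ-1 were 3, against 5 with no filter, 0 with an estimated correlation, 1 with fry (oxidative phosphorylation, none of the 3), 1 with the span trend removed (glycolysis) and 1 to 4 with an array left out. Gene lists lower after PIP-RBPJ-1 were 2, against 1 with no filter, 0 with an estimated correlation, 1 with fry (chromatin regulators), 1 with the span trend removed (G2/M) and 1 to 2 with an array left out. The Notch target list shift was 0.26, 0.175 with no filter (now passing) and 0.225 to 0.295 with an array left out. It was smallest at 0.06 with the stricter filter, and was 0.16 with the span trend removed. With an array left out, the median of 31 of the 37 lists that did not pass moved by over 1.5 times or turned, and 8 turned, against 0 of the 5 that passed. The cause was not tested for these changes unless stated. A list median near 0 moves by over 1.5 times or turns easily, and the 5 lists were selected on these same data. The contrast between passing and other lists is therefore no measure of stability. Counts without overlap follow a looser criterion when an array is left out, since fewer arrays must lie apart. With the replicate block, 0 genes passed (smallest adjusted p 0.344) and the same 5 lists did, 3 higher and 2 lower; the replicate numbers do not pair the samples, since deviations of the groups' replicates correlated at 0.022 and there are 2 pairs. Dim signal limits low genes.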

Other observations

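Tests of DMSO replicate 2 on all 3 patterns, of protein-coding genes alone and of other splits of the arrays on gene span were chosen after the result was seen. In lists that did not pass camera, single genes still lay apart from DMSO on both arrays. The Sonic hedgehog pathway genes GAS1, SMO and GLI1, encoding a co-receptor, the signal transducer and a transcription factor, differed by 0.61 ± 0.16, 0.35 ± 0.10 and 0.49 ± 0.15 on the log2 scale (± SE, n = 2), in a list of 17 genes with a median of 0.01, which turned to -0.045 without DMSO replicate 2 and -0.025 without PIP-RBPJ-1 replicate 1. These 3 are the members with the smallest p, and 10 of the 17 genes were positive and 7 negative. The apoptosis genes BAD, CASP9, BAX and BBC3 were higher when adjusted over the list of 22 genes alone, at 0.52 ± 0.10 for BAD and 0.66 ± 0.15 for CASP9, against 0 over all genes tested. Among axon guidance genes the ephrin genes EFNB1 and EFNB3 differed by 0.53 ± 0.12 and 0.54 ± 0.14, and the netrin receptor gene DCC had a log2 fold change of -0.40 ± 0.11. FGFR3, a receptor tyrosine kinase gene among the astrocyte markers, differed by 0.51 ± 0.11, while CLU and APOE differed by 0.32 ± 0.11 and 0.33 ± 0.11. Of the DNA damage genes, the kinase genes ATR and CHEK1 had log2 fold changes of -0.48 ± 0.10 and -0.27 ± 0.10, and the ligase gene LIG1 one of 0.35 ± 0.11. None of these genes passed over all genes (smallest adjusted p in limma 0.233).

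Shorter genes lay higher and longer genes lower after PIP-RBPJ-1. DMSO replicate 2, unequal value distributions, expression level and small RNA genes were each argued against as the whole cause. Without DMSO replicate 2 the rank correlation of fold change with span was -0.289, after quantile normalization -0.336, within 10 equal bins of mean expression a median of -0.351 (range -0.521 to -0.0902 over the bins), and over protein-coding genes -0.379. Among the 3 splits of the 4 arrays, only the real 1 gave a correlation this far from 0, at -0.336 against 0.0904 for the highest other, and 3 splits are too few for a share under 0.05. A difference in RNA quality or amplification between the groups, GC content, for which no genome was used here, and an effect of the compound on the transcription of long genes may each account for it and stay open.

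Small nucleolar RNAs had higher means after PIP-RBPJ-1. Without DMSO replicate 2 their median log2 fold change was 0.26 (0.255), which argues against that array as the whole cause. Better recovery of short RNA in the treated samples could raise the shorter C/D box class at least as far as the H/ACA box class. The medians were 0.33 over 64 C/D box and 0.50 over 47 H/ACA box genes, a difference of -0.163. Its 95% bootstrap interval, drawn over genes and not arrays, was -0.295 to 0.065 and includes 0. Both classes are short, with median spans of 90 and 135 bases, so better recovery could raise either one further. This comparison therefore cannot tell better recovery and a biological change apart. An effect of the compound stays untested.

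G2 and M phase genes fell as a group, while replication-dependent histone genes rose (median 0.31, 12 of 12 positive) and G1/S genes did not pass (median -0.04), and no biological explanation was tested. The trend with gene span was argued against as the whole cause, since with it removed the list still passed (adjusted p = 6.06e-06, median -0.12), as it did without DMSO replicate 2 (adjusted p = 0.00208, median -0.17). Over its alternatives, the adjusted p of the list reached 0.861 with an estimated correlation. That form of camera had 2 residual degrees of freedom and could hardly call any list. The real split gave this list a camera p of 1.1e-06 and the other splits at least 0.418, and 1 of 3 splits was as extreme, too few splits for a share under 0.05. Likewise 5 lists passed in the real split and 0 in each other split, so 1 of 3 splits called as many, with the same limit. The other splits mix the groups, so any difference between DMSO and PIP-RBPJ-1 widens the spread within them and works against a call.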
